A study of Mus musculus with 11 samples.

How the data were processed

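Messenger RNA of 11 libraries was compared: 3 of cells in normal glucose, 4 in high glucose and 4 in high glucose with Hsp70, all after 5 days. RNA was taken up in Trizol and libraries were made with a stranded SMARTer kit, per the labels. The deposited values, 1 file per library, are in log2 units, read from the values themselves as log2(normalized count + 1): none lies below 0, and the low genes fall in steps near whole reads once the log is undone. The submitters' processing notes name TopHat, edgeR and the mouse genome mm10, without versions. The kind of normalization, the annotation and the handling of reads that fit several genes are not given in the sources used here. In sets 4 and 5 of the deposited files 11.9% of the genes hold 0, the same genes in all 6 libraries, and other undetected genes hold small values above 0. In sets 2 and 3 undetected genes hold 0.

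Each file held 23282 genes. Where a symbol occurred more than once the copy with the highest mean was kept (44 others dropped), which left 23238. Of these, 22197 (95.5%) matched a gene name in GENCODE M21, which gave the positions. Genes with a normalized count of at least 1 in at least 3 libraries were tested, 18248 in all. The normalized counts of a library summed to 24.8 to 27.8 M, and the implied reads were 22.0 to 32.1 M. The ribosomal RNA gene Rn45s took 0.638% to 7.00% of the normalized counts, and the 10 most abundant genes took 8.00% to 13.1%. With that depth the median standard error of a log2 difference was 0.287, 0.265 and 0.287 in the 3 comparisons.

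Differences were tested with limma 3.58.1 in R 4.3.3 on the deposited log2 values, with 3 group means in 1 model, a trended prior and robust variance estimates. P-values were adjusted by Benjamini-Hochberg at 0.05, with no fold minimum. On simulated data in which 200 genes were changed, this recovered 23.0%, 74.3% and 92.3% of changes of 1, 2 and 3 log2 units for high against normal glucose. For Hsp70 against high glucose it recovered 42.3%, 80.6% and 82.5%, and for Hsp70 against normal glucose 35.9%, 67.5% and 88.1%. Unchanged genes were 4 of 124, 4 of 139 and 13 of 140 calls in the 3 comparisons, with 1 simulation each. Single genes were also compared by two-sided exact permutation tests. Every exact permutation test below moved libraries between groups regardless of file set, although libraries of 1 set were correlated. Such p-values treat all libraries as exchangeable, which the sets put in doubt. The gene lists, 29 in all, covered pathways, complexes and markers of cell types, and 27 had at least 5 measured members. They were tested with camera in limma at the preset correlation of 0.01 and, beside it, with an estimated correlation and with fry. In simulated data the list that was moved ranked 1 and no other was called. Each simulated gene and library was drawn independently, without file sets or correlation between genes. In the real data the estimated correlation of a list reached 0.779 (interferon-stimulated genes). The simulation therefore cannot show how often lists are called by chance in these data. No list was called with an estimated correlation or by fry in any of the 3 comparisons; at the preset correlation 2, 5 and 8 were. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

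The comparisons, the limma and list tests, the lists and the naming of genes were fixed before the data were examined. In each comparison the rule names the 8 genes with the largest rise and the 8 with the largest fall among those that pass, above the median expression and without predicted-gene names. Where fewer pass it goes on by the smallest unadjusted p, as values that did not pass. It adds 13 genes in every comparison (Cth, Cbs, Mpst, Hspa1a, Hspa1b, Nos3, Pecam1, Cdh5, Hmox1, Txnip, Cxcl12, Angpt1 and Vegfa) and up to 4 members of each list described, by smallest unadjusted p. The plan named adjustment over all genes tested. It did not name an adjustment over these 13 genes alone, nor the exact permutation tests.

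The labels give no batch. Sample titles number the normal glucose libraries from 1 to 3, whereas the names of the deposited files put them in sets 3 to 5. Taking out the group means, the correlation of 2 libraries that share a file set was 0.594, 0.302 and 0.285 for high and normal glucose in sets 3, 4 and 5, and 0.422, 0.691, 0.0586 and 0.262 for Hsp70 and high glucose in sets 2 to 5. For Hsp70 and normal glucose it was 0.458, 0.0219 and 0.372. By title number it was -0.224, -0.357 and 0.137 for high and normal glucose, and -0.24, -0.26 and -0.127 for Hsp70 and normal glucose. The file set was therefore tried as a block and is given beside the main values. Libraries of 1 set were not copies of each other: the smallest mean absolute log2 difference between any 2 was 0.33.

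The alternatives fixed beforehand were a block by file set or by title number, sets 3 to 5 only, sets 2 and 3 or sets 4 and 5 alone, no filter, a filter at 10, quantile normalization, median centring, limma without the trend, sample weights, an added constant of 0.1 or 5, only the groups compared, an estimated correlation for the lists, and leaving out each library in turn. Leaving out set 3, with and without a block, was added after the data were seen. A surrogate variable was also planned and was not run. Tests of raw counts were planned only for the case that counts were deposited.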

Results

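Messenger RNA was measured by RNA sequencing in mouse cells that the labels call cavernous endothelial cells, which line the blood spaces of the penis, after 5 days in culture. The 11 libraries fell into 3 groups: normal glucose (n = 3), high glucose (n = 4) and high glucose with added Hsp70, a heat shock chaperone protein (n = 4). The labels give neither the glucose concentrations nor the form or dose of Hsp70. The normalized counts of a library summed to between 24789387 and 27807569, and the spacing of the low values put the reads behind them at 22.0 to 32.1 M. Values below are log2(normalized count + 1), and differences are log2 differences with the standard error from limma. Nothing in the labels says that the replicates were separate cultures or animals, so every p measures only the spread between these samples. The names of the deposited files also number the libraries by set: sets 3, 4 and 5 held 1 library of each group, and set 2 held 1 high glucose and 1 Hsp70 library.

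The sets differed more than the groups did: limma called 2165 of 18248 genes different among the 4 sets, and 0 in each comparison of groups given below. Libraries of set 3 lay at 72.1 to 81.0 on the first principal component, which held 34.8% of the variance, and the other 8 libraries lay between -42.3 and -17.3. On the second component, with 16.5% of the variance, Hsp70 replicate 3 lay farthest out at 70.3, the others between -47.5 and 34.2. Taking out the group means, its correlation with the high and normal glucose libraries of its set was 0.0586 and 0.0219. Without it limma still called 0 genes in each comparison, and 9 lists in place of 5 and 9 in place of 8 in those that use it. Markers of macrophages and other leukocytes and of endothelial cells were higher in set 3. Adgre1, the macrophage surface protein F4/80, was 6.33 higher in set 3 than in the other sets (adjusted p = 1.14e-05, limma), and Pecam1, the endothelial adhesion protein CD31, was 5.46 higher (adjusted p = 1.22e-06, limma). By limma, 15 of 17 leukocyte markers were higher (adjusted p = 0.000379 for the list with an estimated correlation), as were 18 of 26 endothelial markers (also 0.000379) and 7 of 14 Schwann cell and nerve markers (0.00837). The 31 of 39 interferon-stimulated genes that were lower in set 3 gave adjusted p = 0.0621 for their list with an estimated correlation. Pecam1 stood at 8.86 to 9.07 in the 3 libraries of set 3 and at 2.68 to 4.51 in the other 8. The fibroblast matrix gene Dcn stood at 15.17 to 17.63 in all 11. It too was higher in set 3, at 17.1 or above against at most 16 elsewhere. In the 8 libraries outside set 3 the endothelial markers had a median normalized count of 13.8 and the fibroblast markers 2370. The endothelial genes Tie1, Cldn5 and Robo4 were among the lowest there, at log2 medians of 0.58, 0.08 and 0.28. Others of that list stood high in the same libraries, with Cd34, Eng and Clec14a at log2 medians of 12.1, 11.2 and 9.79. In set 3 the 2 medians of the markers were 80.5 and 6660. Over all genes, limma found 1537 to differ between set 3 and the rest, 1102 of them higher. This contrast was chosen after the values were seen. Here and below it counts the 3 libraries of set 3 as separate samples, though libraries of 1 set were correlated. Set 3 is 1 of 4 sets, so these p-values do not measure the spread between sets. Each group held 1 library of set 3, which was 1 of 3 in normal glucose and 1 of 4 in the other groups.

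**Figure D1:**
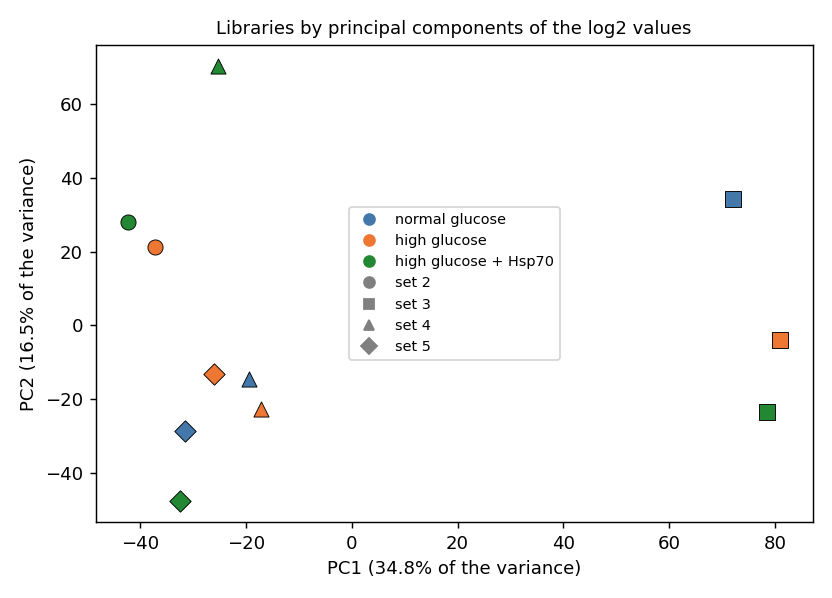
Each point is 1 library placed by the first 2 principal components of the log2 values of the 18248 genes tested (34.8% and 16.5% of the variance), with the group and the file set marked. The 3 libraries of set 3 stand apart from the other 8 on the first component, whatever their group.

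The first comparison asks what high glucose did to these cells. Txnip, which binds thioredoxin and is induced by glucose, was 1.18 higher in high glucose (SE 0.235, limma), at 11.89 ± 0.0684 (SD, n = 4) against 10.72 ± 0.625 (SD, n = 3), and every high glucose library lay above every normal glucose library. Its relative Arrdc4, also a target of the glucose-sensing factor ChREBP, gave 0.44 (SE 0.175, adjusted p = 1.00 by limma). Like Txnip, it did not pass over all genes tested. The stress-inducible Hsp70 genes Hspa1a and Hspa1b were 0.63 (SE 0.163) and 0.59 (SE 0.173) higher, Hspa1a at 9.02 ± 0.205 (SD, n = 4) against 8.39 ± 0.121 (SD, n = 3). Bhlhe40, a transcriptional repressor of the clock and a member of the hypoxia response list, gave -0.54 (SE 0.164). Like Hspa1a and Hspa1b, it did not pass over all genes tested. Within sets 3, 4 and 5, high minus normal glucose was 1.78, 0.71 and 1.04 for Txnip, 0.66, 0.45 and 0.48 for Hspa1a, 0.64, 0.37 and 0.51 for Hspa1b, and -0.33, -0.90 and -0.42 for Bhlhe40.

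Over all 18248 genes limma called 0 in this comparison, with 185 at an unadjusted p under 0.05 (76 higher, 109 lower). Independent libraries without any change would give 912, but libraries of 1 set were correlated. Other splits of the same libraries, run after the values were seen, gave a median of 371.5 and up to 1574. With the file set as a block limma also called 0, with 636 at an unadjusted p under 0.05. The median standard error was 0.287 without the block and 0.222 with it. Differences between sets thus widened the error without the block, and 0 calls do not show that no gene changed. Adjusted over the list alone, the 13 genes fixed for the study's question gave 3 that passed by limma: Txnip (adjusted p = 0.00385), Hspa1a (0.0138) and Hspa1b (0.0234). That narrower adjustment was not in the plan. With the set as a block these were 0.00651, 0.00811 and 0.0303, at differences of 1.14, 0.54 and 0.50. In a two-sided exact permutation test each of the 3 gave p = 0.0286, the smallest that 35 splits allow, and 0.124 after adjustment over the 13. Those splits mix the file sets, whose libraries were correlated. Txnip passed over the list alone under all 27 alternative settings (adjusted p by limma from 0.000737 to 0.0463), and its difference was 1.83 in sets 2 and 3 alone. Hspa1a passed under 21 (0.0072 to 0.347) and did not without normal glucose replicate 1 (0.0702) or 3 (0.05), with set 3 left out (0.128, or 0.139 with a block as well; chosen after the data were seen), or in sets 2 and 3 (0.172) or 4 and 5 alone (0.347). Hspa1b passed under 18 (0.0138 to 0.437) and did not without normal glucose replicate 1 (0.0877) or 3 (0.111) or high glucose replicate 1 (0.0801) or 3 (0.0529), with set 3 left out (0.174, or 0.213 with a block), in sets 3, 4 and 5 only (0.05), or in sets 2 and 3 (0.172) or 4 and 5 alone (0.437). Hspa1a and Hspa1b are near-identical copies on chromosome 17 (mm10, 34969190 to 34972156 and 34956436 to 34959238), and how the authors counted reads that fit both is not given. Txnip (chromosome 3, 96557957 to 96561883) lies wholly inside the antisense gene Gm15441, which read 1.21 higher (SE 0.275), and the strand used for counting is not given.

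None of the other 10 genes of the study's question passed when adjusted over the list alone. Cth, the cystathionine gamma-lyase of the series title, which makes hydrogen sulfide, gave -0.22 (SE 0.526). Its fellow hydrogen sulfide enzymes Cbs and Mpst gave 0.18 (SE 0.481) and -0.07 (SE 0.292). The chemokine Cxcl12 gave -0.35 (SE 0.244), Vegfa -0.09, Angpt1 0.18 and the heme oxygenase Hmox1 -0.05. The endothelial genes Nos3, Pecam1 and Cdh5 gave 0.19, -0.21 and -0.21 with errors of 1.34, 1.84 and 1.01, the spread being that between the sets. Other genes that the naming rule picked, none of which passed, were Sept6 (0.40), Papss1 (0.29), Mat2b (0.32) and AI597479 (0.32) on the higher side. Appl2 (-0.56), Plin4 (-0.54), Mlph (-0.53), Ulk3 (-0.48), Mmp11 (-0.46), Sh3rf3 (-0.39) and Wbscr17 (-0.37) were on the lower side.

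By limma's camera with its preset correlation, 2 of 27 gene lists were called. Cytosolic heat shock chaperones were called higher (adjusted p = 0.0111), with 15 of 21 members above 0 and a median of 0.03. Hspa1a and Hspa1b, the near-identical pair given above, were its 2 members at an unadjusted p under 0.05 by limma. Hspa1l gave 0.52 and Dnaja1 0.24, neither past a threshold. The hypoxia response was called lower (adjusted p = 0.0384), with 19 of 24 members below 0, such as Hk2 (-0.36) and Ankrd37 (-0.36). Both calls were lost with an estimated correlation (adjusted p = 0.998 with an estimated correlation) and with the set as a block (adjusted p = 0.583 for each); over 17 alternatives the adjusted p ran from 0.000133 to 0.998 and from 0.000135 to 0.998. With the block 3 other lists were called: ATF4 targets lower (adjusted p = 2.15e-08, median -0.38), immediate early genes lower and fibroblast markers higher (0.0377 each), all 3 lost with an estimated correlation (adjusted p = 0.938 with an estimated correlation). The block fit also draws on set 2, which held no normal glucose library and held Hsp70 replicate 1, where the ATF4 mean was the highest of all libraries (11.22). Within sets 3, 4 and 5 the ATF4 median of high minus normal glucose was -0.184, -0.156 and -0.417, and without the block it was -0.139 over all libraries (adjusted p = 0.257). The chaperone call ended without normal glucose replicate 3 (0.173) or high glucose replicate 1 (0.352), and the hypoxia call without normal glucose replicate 1 (0.426) or 2 (0.0507) or high glucose replicate 1 (0.529) or 3 (0.361). The hypoxia mean, -0.139 with all libraries, was then -0.0538, -0.165, -0.0732 and -0.102, so it was not smaller without normal glucose replicate 2. Set 3, 1 of 3 normal glucose and 1 of 4 high glucose libraries, lay above the other sets for the hypoxia list (mean 0.344, adjusted p = 0.00168; adjusted p = 0.271 with an estimated correlation). The hydrogen sulfide list was not called (adjusted p = 0.995).

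**Figure D2:**
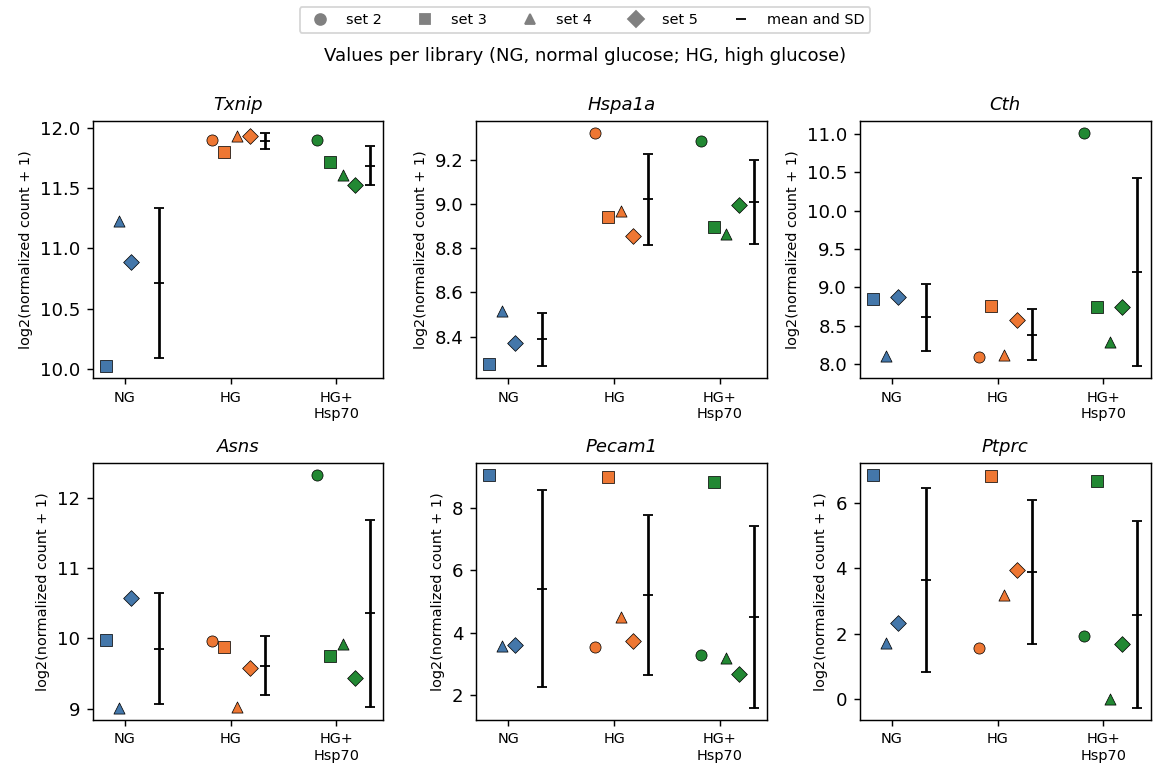
Log2(normalized count + 1) of Txnip, Hspa1a, Cth, Asns, Pecam1 and the leukocyte gene Ptprc in each library by group, with the file set as the symbol and the group mean and standard deviation beside. All 8 high glucose and Hsp70 libraries lay above the 3 normal glucose libraries for Txnip and Hspa1a, and 1 Hsp70 library stood far above the others for Cth (11.01).

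The second comparison asks what Hsp70 did to cells in high glucose. Cth stood at 9.20 ± 1.22 (SD, n = 4) with Hsp70 against 8.39 ± 0.328 (SD, n = 4) in high glucose alone, a difference of 0.81 (SE 0.487; two-sided exact permutation p = 0.2). It came from Hsp70 replicate 1, at 11.01 where the other 3 libraries read 8.30 to 8.75: within sets 2 to 5 the difference was 2.91, -0.01, 0.17 and 0.18, and without that library it was 0.21. Hspa1a and Hspa1b gave -0.01 (95% interval -0.34 to 0.32) and -0.00147 (-0.35 to 0.35). Txnip gave -0.21 (SE 0.217; two-sided exact permutation p = 0.0571, and 0.742 after adjustment over the 13 genes). Nos3 (-0.76, SE 1.24), Pecam1 (-0.71, SE 1.70), Cdh5 (0.27, SE 0.935), Vegfa (-0.15, SE 0.136) and Cxcl12 (-0.15, SE 0.226) did not pass. These errors include the differences between sets. With the set as a block the adjusted p over the 13 genes was 0.625, 0.405, 0.626, 0.625 and 0.625 by limma.

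Limma called 0 of the 18248 genes, with 136 at an unadjusted p under 0.05 (69 higher, 67 lower), and 0 with the set as a block, with 305 at that level. None of the 13 genes passed when adjusted over the list alone. The count of 0 became 3 without Hsp70 replicate 2, for Ssxb3, Ssxb6 and Gm14459, members of an X-linked family of germ cell genes, higher by 4.55, 4.43 and 4.71 (adjusted p = 0.0406 each, limma). These were named after their values were seen. The rule named Osbpl7 (0.39), Taf15 (0.41), Dnajc17 (0.38), Thoc5 (0.35) and Rab3a (0.34) on the higher side, together with Nelfa, Ppih and Sh3rf3 at 0.33, 0.32 and 0.32. Lrrc19 (-0.42), Rhou (-0.47), Stk17b (-0.39), Capn6 (-0.35), Mkks (-0.35), Ckap2l (-0.34), Spice1 (-0.33) and the translation repressor Pdcd4 (-0.29) stood on the lower side, and none of the 16 passed.

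Camera with its preset correlation called 5 of 27 lists. Targets of ATF4, the factor that switches on amino acid synthesis under stress, were called higher (adjusted p = 7.57e-05), with 27 of 30 members above 0: Asns, the asparagine synthetase, gave 0.75 (SE 0.565), Stc2 0.45, Atf5 0.41 and Pck2 0.39, none past a threshold. Their median was 0.861 in set 2 but -0.0768, 0.392 and -0.202 in sets 3, 4 and 5, and without Hsp70 replicate 1 the mean of the list turned from 0.29 to -0.12 (adjusted p = 0.236). Nuclear-encoded respiratory chain genes were called higher (adjusted p = 0.02; 34 of 48 above 0; Ndufs6 0.19 and Atp5h 0.26). The call ended without high glucose replicate 4 (0.777) or Hsp70 replicate 1 (0.642) or 3 (0.729). Genes of p53 and apoptosis were called lower (adjusted p = 0.02; 22 of 27 below 0; Sesn1 -0.28 and Casp9 -0.29), but not without high glucose replicate 1 (0.376) or 4 (0.183) or Hsp70 replicate 2 (0.859). Cholesterol synthesis genes were called lower (adjusted p = 0.02; 20 of 25 below 0; Hmgcs1 -0.28 and Idi1 -0.26), but not without high glucose replicate 1 (0.272) or 4 (0.249) or Hsp70 replicate 1 (0.883) or 2 (0.455). Cell cycle genes were called lower (adjusted p = 0.0367, 25 of 40 below 0, the mitotic cyclin Ccnb1 at -0.46, SE 0.194), but not with the set as a block (0.059), nor without high glucose replicate 1 (0.891) or 3 (0.0656) or Hsp70 replicate 1 (0.11) or 2 (0.946). Leaving out those libraries put the mean, -0.0777 with all, at -0.0128, -0.0654, -0.0777 and -0.018. All 5 calls were lost with an estimated correlation (adjusted p = 0.988 with an estimated correlation), which is also the highest value over the 17 alternatives of each list. The block also called genes of NF-kB and leukocyte recruitment lower (adjusted p = 0.00937) and leukocyte markers lower (0.0321), both lost with an estimated correlation (adjusted p = 0.608 with an estimated correlation). The hydrogen sulfide list was not called (adjusted p = 0.313), nor were the endothelial (0.981), nitric oxide (0.313) and neurotrophic (0.981) lists.

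**Figure D3:**
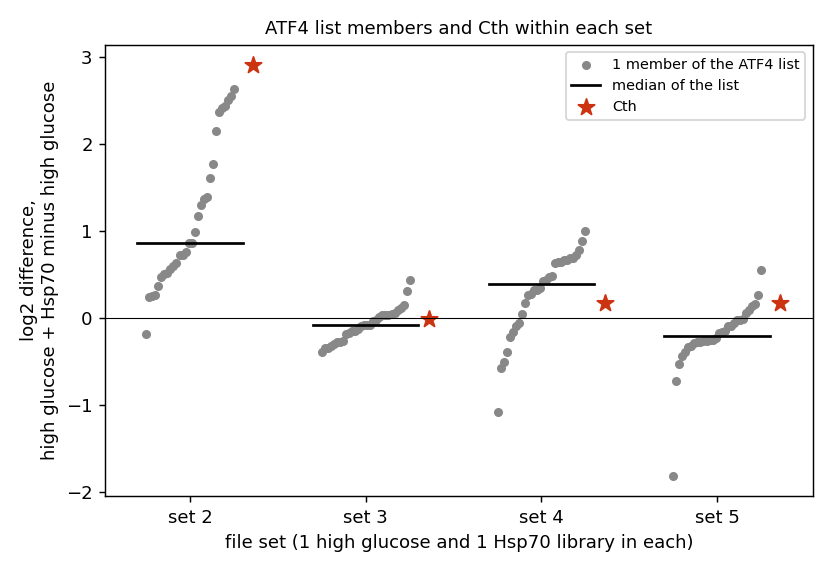
Hsp70 minus high glucose in log2 within each of the 4 file sets, for each of the 30 measured ATF4 genes, with the median as a line and Cth as a star. The median is 0.861 in set 2, where 29 of the 30 genes lie above 0, and -0.0768, 0.392 and -0.202 in sets 3, 4 and 5.

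The third comparison sets Hsp70 in high glucose against normal glucose, that is, whether treated cells were back at the starting level. Txnip was still 0.97 higher than in normal glucose (SE 0.235, limma), Hspa1a 0.62 (SE 0.163) and Hspa1b 0.58 (SE 0.173), while Arrdc4 gave 0.42 (SE 0.175). None of these passed over all genes tested. Cth gave 0.59 (SE 0.526; two-sided exact permutation p = 0.714) and -0.02 without Hsp70 replicate 1. The clock repressor Bhlhe40, of the hypoxia response list, gave -0.53 (SE 0.164) and the lipid droplet gene Plin4 -0.66 (SE 0.228). Within sets 3, 4 and 5 Txnip differed from normal glucose by 1.70, 0.37 and 0.64.

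Limma called 0 of the 18248 genes, with 178 at an unadjusted p under 0.05 (73 higher, 105 lower), and 0 with the set as a block, with 587 at that level. Without Hsp70 replicate 2 it called 3, again Ssxb3, Ssxb6 and Gm14459 (4.81, 4.69 and 4.67; adjusted p = 0.0448 each). Adjusted over the list alone, Txnip (0.0158), Hspa1a (0.0158) and Hspa1b (0.0238) passed by limma among the 13 genes. In a two-sided exact permutation test Txnip and Hspa1a gave p = 0.0286, or 0.124 after adjustment over the 13, and Hspa1b gave p = 0.0571, or 0.186. Txnip passed under 23 of 27 alternatives (0.00275 to 0.309), failing when set 3 was left out (0.129, or 0.141 with a block as well; chosen after the data were seen), with sample weights (0.051) and in sets 4 and 5 alone (0.309). Its difference was 0.62 with set 3 left out, or 0.57 with a block as well, and it was 0.63 without normal glucose replicate 1, 0.64 with sample weights, 0.51 in sets 4 and 5 alone and 1.79 in sets 2 and 3 alone. Hspa1a passed under 20 (0.011 to 0.309), not without normal glucose replicate 1 (0.079) or 3 (0.056), with set 3 left out (0.129, or 0.141 with a block), with sample weights (0.0505), or in sets 2 and 3 (0.193) or 4 and 5 alone (0.309). Hspa1b passed under 16 (0.011 to 0.46), not without normal glucose replicate 1 (0.0888) or 3 (0.113) or Hsp70 replicate 1 (0.0683) or 4 (0.0561), with set 3 left out (0.158, or 0.239 with a block), with sample weights (0.051), with only the groups compared (0.066), in sets 3, 4 and 5 only (0.0617), or in sets 2 and 3 (0.193) or 4 and 5 alone (0.46). The rule also named Prune2 (0.68), Ndufaf5 (0.49), Nelfa (0.39) and Tesk2 (0.33), and on the lower side Ankrd37 (-0.64), Slc16a9 (-0.58), Fyb (-0.54), Fam84a (-0.38) and Cerk (-0.37), none of which passed. Cxcl12 gave -0.50 (SE 0.244) and Vegfa -0.24 (SE 0.147; two-sided exact permutation p = 0.0286, and 0.124 after adjustment over the 13 genes).

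Camera with its preset correlation called 8 of 27 lists. Heat shock chaperones were called higher (adjusted p = 2.19e-05, 18 of 21 above 0, Hspa4l at 0.64), and not without Hsp70 replicate 1 (0.0553). Hspa1a and Hspa1b were again the 2 members at an unadjusted p under 0.05 by limma. The hypoxia response was called lower (adjusted p = 2.19e-05; 20 of 24 below 0, Ankrd37 at -0.64 and Hk2 at -0.38), a call that no single library ended. Its mean was -0.195, but -0.11 without normal glucose replicate 1, -0.117 without Hsp70 replicate 1 and -0.123 with the set as a block (median -0.233, and -0.0635 with the block). With the block and set 3 left out, chosen after the data were seen, the call ended (0.0861). Cholesterol synthesis was called lower (adjusted p = 0.00011; 24 of 25 below 0, Hmgcs1 at -0.41), and not without Hsp70 replicate 1 (0.538). Interferon-stimulated genes were called higher (adjusted p = 0.00819; 34 of 39 above 0), and ATF4 targets as well (adjusted p = 0.042; 21 of 30 above 0). Glycolysis (adjusted p = 0.0152; 20 of 22 below 0, Slc2a1 at -0.31), angiogenic factors and receptors (adjusted p = 0.0345; 23 of 33 below 0, Flt1 at -0.57) and the cell cycle (adjusted p = 0.0434; 28 of 40 below 0, Bub1 at -0.77) were called lower. No call held with an estimated correlation (adjusted p = 0.694 with an estimated correlation for chaperones, hypoxia, cholesterol and angiogenic genes, and 0.822 for the other 4). With the set as a block, chaperones (0.00949), hypoxia (0.00545), cholesterol (0.00554) and the cell cycle (0.00545) were called and the other 4 were not. The block also called genes of NF-kB and leukocyte recruitment (0.0101), of p53 and apoptosis (0.0035) and immediate early genes (0.00135) lower, all 3 lost with an estimated correlation (adjusted p = 0.556 with an estimated correlation). Over the 17 alternatives of each list the highest adjusted p was 0.694 for chaperones, hypoxia, cholesterol and angiogenic genes, 0.822 for ATF4, 0.845 for glycolysis and interferon genes, and 0.874 for the cell cycle. Leaving out normal glucose replicate 1 ended the interferon (0.845), glycolysis (0.845), angiogenic (0.276), cell cycle (0.845) and ATF4 (0.235) calls. Leaving out Hsp70 replicate 1 ended the interferon (0.666), glycolysis (0.635), angiogenic (0.249) and cell cycle (0.0638) calls and turned the ATF4 mean from 0.16 to -0.25 (adjusted p = 0.000714). Further endings came without Hsp70 replicate 3 (interferon 0.594, angiogenic 0.343, ATF4 0.0597), Hsp70 replicate 4 (interferon 0.173, glycolysis 0.44, angiogenic 0.147), Hsp70 replicate 2 (cell cycle 0.874), normal glucose replicate 2 (ATF4 0.408) and high glucose replicate 1 (cell cycle 0.052). Some of these endings came without a smaller shift. The ATF4 mean was 0.159 with all libraries and 0.236 without Hsp70 replicate 3. The cell cycle mean was -0.0992 with all libraries and also without Hsp70 replicate 1 or high glucose replicate 1. Set 3, which was 1 of 3 normal glucose and 1 of 4 Hsp70 libraries, lay above the other sets for the hypoxia (mean 0.344, adjusted p = 0.00168), glycolysis (0.288, 0.00729) and angiogenic lists (1.03, 0.0015) and below them for interferon genes (-0.962, 5.21e-28). With an estimated correlation none of the 4 was called in set 3 (adjusted p = 0.271, 0.495, 0.0644 and 0.0621 with an estimated correlation). Leukocyte markers, high in set 3, had 13 of 17 members below 0 with a median of -0.51 and were not called (adjusted p = 0.417), nor was the hydrogen sulfide list (0.363).

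The last question is whether Hsp70 and high glucose moved genes in opposite directions. No gene passed in both comparisons with opposite signs (0 by limma). At an unadjusted p under 0.05 there were 7 genes higher with high glucose and lower with Hsp70, and 6 the other way, where independent comparisons would give 0.279 and 0.412. The high glucose libraries enter both comparisons with opposite signs. Of 100 groupings, the real one included, 100 gave at least 13 such genes when all libraries were relabelled (median of the others 75), and 99 when they were relabelled within the file sets (median 29). Of the 13, 9 were opposite in every set, a count reached by 98 of 100 groupings within the sets (median 20). These groupings, and the 2 genes named next, were chosen after the values were seen. Cdkl1, a kinase gene of low level here (0.10 to 3.67), gave -1.81 with high glucose (SE 0.498; adjusted p = 1.00, limma) and 2.62 with Hsp70 (SE 0.461; adjusted p = 1.00). Within sets 3, 4 and 5 it differed by -1.99, -2.26 and -2.11 with high glucose, and within sets 2 to 5 by 2.11, 2.39, 2.46 and 3.54 with Hsp70. The immediate early gene Egr2 gave -1.41 (SE 0.652) and 1.10 (SE 0.604), not past an unadjusted p of 0.05 in either (0.0511 and 0.0926, limma), with -0.74, -0.91 and -1.08 and with 1.58, 0.59, 1.89 and 0.36 within the sets. Across genes, which are not independent replicates, the correlation of the differences was r = -0.425, against a mean of -0.461 in simulated unchanged groups and -0.464 among relabelled samples (-0.776 to -0.00687). With the high glucose libraries divided so that no library served both comparisons, r was 0.192 on average (0.107 to 0.289). Relabelling within the file sets, chosen after the values were seen, gave at least that in 217 of all 432 groupings (mean of the others 0.173, from -0.114 to 0.308). Txnip, Hspa1a and Hspa1b, the 3 genes that stood out with high glucose, differed between Hsp70 and high glucose by -0.21, -0.01 and -0.00147.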

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

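Of the tests in this part, the shift of the whole library and the sign of the ATF4 genes per set were chosen only after the result was seen. In each group of 4 libraries the highest and the lowest value of each named gene and the mean of each list were compared with the nearest other value by Dixon's ratio. Of 244 such groups (95 genes and 27 lists), 28 had a library far from the other 3, where independent groups would give 12.2. The groups were not independent: genes were picked by their p in these libraries, and some are in the lists too. The Ssxb genes, named after their values were seen, were also among the 95. The excess over 12.2 is therefore not a test. Groups of 3 were not looked at.

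Cth, the cystathionine gamma-lyase, read 11.01 in Hsp70 replicate 1 and 8.30 to 8.75 in the other 3 Hsp70 libraries. In the same library the asparagine synthetase Asns read 12.33 (9.43 to 9.92 in the others), the serine synthesis enzyme Psat1 read 11.48 (8.19 to 8.42) and the glycolysis regulator Pfkfb4 read 5.79 (6.48 to 6.55). The tables argue against a shift of the whole library: the genes above the median expression had a median of 0.0317 between this library and its high glucose partner of set 2, below the lower quartile of the ATF4 genes, 0.529. An effect of Hsp70 common to the sets would put the ATF4 median above 0 in all 4 sets. It lay above 0 in 2 of 4, so a rise in every set was not seen. Without Hsp70 replicate 1 the mean of the list was -0.118. The sign test cannot decide on a common effect, since 4 sets cannot give an exact sign test p under 0.125. Set 2 holds only 1 Hsp70 library, so a state of this 1 library and an effect of Hsp70 in set 2 cannot be told apart.

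Libraries of set 3 gave most of the other values. In high glucose replicate 2 the vascular growth factor Angpt1 read 11.64 (10.48 to 10.61 in the other 3), Osbpl7 read 8.131 (7.92 to 7.95), and the apelin receptor Aplnr read 2.588 (0 to 0.08). Lower there were the sterol regulator Insig1 at 10.15 (10.68 to 10.77), Eno2 at 9.127 (9.61 to 9.66) and the interferon-stimulated genes Ifi44 at 11.96 (12.92 to 13.09), Ifi35 at 9.427 (10.11 to 10.19) and Oas3 at 6.122 (7.30 to 7.51). Ssxb3 and Ssxb6 read 1.174 and 1.182 there (up to 0.19 in the others). Pecam1 read 8.856 in Hsp70 replicate 2 (2.68 to 3.27).

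List means stood apart in the same 2 libraries. Leukocyte markers averaged 7.486 in high glucose replicate 2 and 7.191 in Hsp70 replicate 2 (3.37 to 3.85 and 3.16 to 3.61 in the others of each group), and endothelial markers averaged 6.59 and 6.535 (4.06 to 4.21 and 4.10 to 4.24). Angiogenic factors and receptors averaged 8.916 and 8.964 (7.77 to 7.92 and 7.71 to 7.89). Neurotrophic factors averaged 8.639 (8.06 to 8.14) and Schwann cell and nerve markers 7.268 (5.25 to 5.57) in high glucose replicate 2. In Hsp70 replicate 2 smooth muscle markers averaged 8.418 (7.48 to 7.54) and interferon-stimulated genes 10.28 (11.31 to 11.47).

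Of the remaining values, the translation repressor Pdcd4 read 10.17 in high glucose replicate 1 (10.34 to 10.35). Mkks read 7.882 in Hsp70 replicate 4 (8.30 to 8.39). The ATP synthase subunit Atp5o read 12.09 in Hsp70 replicate 3 (11.61 to 11.68).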

How the results depend on the processing

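The settings that leave out set 3 were the only ones chosen after the data were seen. The count of 0 genes by limma held in all 3 comparisons under every alternative run, except that leaving out 1 library at a time gave 0 to 3 genes for Hsp70 against high glucose and 0 to 3 for Hsp70 against normal glucose (3 without Hsp70 replicate 2 in both). The 0 genes past the threshold in opposite directions held throughout. No named gene with an unadjusted p under 0.05 changed sign; 139 values of named genes above that p did under some alternative, against 3370 that kept their direction. Among values of the called lists, 165 kept the call, 82 lost it and 8 turned direction. Direction here is that of the camera test, which can differ from the sign of the mean.

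The number of lists called for high against normal glucose, 2, was 1 without a filter, 5 with set 3 left out (also 5 with a block), 0 with an estimated correlation, and 1 to 10 when single libraries were left out (1 without high glucose replicate 1, 10 without high glucose replicate 2). For Hsp70 against high glucose, 5, it was 2 with set 3 left out (also 2 with a block), 0 with an estimated correlation and 2 to 9 (2 without Hsp70 replicate 1, 9 without high glucose replicate 2 or 3 or Hsp70 replicate 3 or 4). For Hsp70 against normal glucose, 8, it was 5 without a filter, 2 with set 3 left out and a block, 0 with an estimated correlation and 3 to 14 (3 without Hsp70 replicate 1, 14 without normal glucose replicate 3). The cause was not tested.

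Mean differences that turned were these. For Hsp70 against high glucose, single libraries left out gave -0.118 to 0.477 for ATF4 targets (-0.118 without Hsp70 replicate 1), -0.2 to 0.0136 for cholesterol synthesis (0.0136 without Hsp70 replicate 1), -0.186 to 0.0121 for p53 and apoptosis genes (0.0121 without Hsp70 replicate 2) and -0.0133 to 0.143 for the respiratory chain (-0.0133 without Hsp70 replicate 3). For Hsp70 against normal glucose, ATF4 targets gave -0.106 with the set as a block, -0.0868 with that block and set 3 left out, and -0.252 to 0.343 with single libraries left out (-0.252 without Hsp70 replicate 1). Without normal glucose replicate 1 angiogenic genes gave 0.0541 (range -0.51 to 0.0541) and interferon-stimulated genes -0.016 (range -0.016 to 0.419). Cell cycle genes gave 0.0141 with set 3 left out and -0.00646 with a block as well, where the test but not the mean turned. The cause was not tested. A surrogate variable as a covariate, planned before, was not run. Median centring and quantile normalization moved the median of all genes by under 0.1. With 3 or 4 libraries a group, changes of 1 log2 unit were recovered in 23.0% to 42.3% of simulated genes, drawn without file sets. Smaller changes were mostly beyond reach there.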

Other observations

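Of the tests in this part, those of other groupings of the libraries, of the scaling of set 3, of undetected genes and of other triples of libraries were chosen only after the results were seen. The marker genes added to the leukocyte and endothelial lists and the searches for shared sequence and for other genes of the Ssxb pattern were written down before their results. In set 3 the platelet and macrophage chemokine Pf4 was 6.28 higher than in the other sets (adjusted p = 4.77e-06, limma), the actin bundler Lcp1 5.43 and the macrophage mannose receptor Mrc1 3.51. Among vascular genes the capillary lipoprotein binder Gpihbp1 was 5.20 higher, Adgrl4 3.95, Adgrf5 3.34 and Cd93 2.82. Median normalized counts in set 3 and in the other sets were 121 and 6.46 for leukocyte markers, 80.5 and 13.8 for endothelial markers, 181 and 41.3 for Schwann cell and nerve markers, 462 and 162 for smooth muscle markers, and 6660 and 2370 for fibroblast markers.

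Fgf21, a stress hormone and known ATF4 target, read 2.78, 1.76, 3.17 and 0.03 in the 4 Hsp70 libraries and at most 0.09 in the other 7. By limma it was 1.91 higher than in high glucose alone (SE 0.625; adjusted p = 1.00), and it was singled out after its values were seen.

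The stand of set 3 apart from the rest was weighed first. A scaling factor per library is argued against, since the median of all genes was -0.00487 while that of the leukocyte markers was 4.90. The different handling of undetected genes is argued against too, since set 2, whose files treat them like set 3, had a leukocyte median of -0.263 against sets 4 and 5. RNA of leukocytes may have entered set 3, where Lyz2, their most abundant marker, stood at a median of 11.4 against 6.91: of 15 further leukocyte genes 10 were higher and 1 lower, and of the 17 markers 12 also read at least 1 in the other sets and 0 are in another list. More RNA of endothelial cells, the cell type of the labels, may have as well, with Cdh5 at 9.45 against 6.63, 8 of 13 further genes higher and 0 lower, and 19 of the 26 markers seen in the other sets and 5 in another list. Both counts of further genes fell short of the 8 in 10 set beforehand, so both explanations stay open; the labels name no sort that would remove leukocytes and do not say what set 3 was.

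Ssxb genes with Hsp70 were weighed next. The 5 genes Ssxb2, Ssxb3, Ssxb6, Ssxb8 and Gm14459, between 8454345 and 8690844 of chromosome X (mm10), averaged 5.68, 4.49 and 3.60 in Hsp70 replicates 1, 3 and 4, but 0.561 in replicate 2, and at most 0.706 in the other 7 libraries (two-sided exact permutation p = 0.0571 against high glucose, n = 4). Reads shared between the copies may make them count as 1 signal, since 27.1% of their 50-base windows occur in another of the 5. Detection of silent genes in any 3 libraries was rare: 1 of 164 other triples of libraries (that of set 3, with 47 genes) held any gene seen only there. The 3 Hsp70 libraries were looked at because the family had been seen in them, and its copies may be 1 signal. The other triples therefore cannot exclude a single chance event. Sporadic detection limited to these 3 libraries stays open, with 0 genes outside the family seen only in them, and an effect of Hsp70 stays open as well, though replicate 2 does not show it.

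Other groupings of the same libraries were counted last. With a real count of 0 genes by limma in each comparison, 35 of 35 splits match it whatever the data, so these splits say nothing of the gene counts (highest others 0, 3 and 375). At an unadjusted p under 0.05, 25 of 35 splits for high against normal glucose gave as many genes as the real 185 (highest other 1574), 35 of 35 for Hsp70 against high glucose as many as the real 136 (highest other 2980), and 34 of 35 for Hsp70 against normal glucose as many as the real 178 (highest other 3589). For the lists, 33 of 35 splits gave as many as the real 2 for high against normal glucose (highest other 15), 28 of 35 as many as the real 5 for Hsp70 against high glucose (highest other 16), and 18 of 35 as many as the real 8 for Hsp70 against normal glucose (highest other 15). Chance cannot be excluded for these counts of lists. The split with 375 genes, picked as the highest, set normal glucose replicates 2 and 3 and Hsp70 replicates 2 and 4 against the other 3. It runs along the second principal component: those 4 lay at -14.48, -28.62, -23.44 and -47.54. The other 3, normal glucose replicate 1 and Hsp70 replicates 1 and 3, lay at 34.16, 27.99 and 70.29. The component was drawn from the same values, so it is no separate support for the split.

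These splits mix the file sets, so those that swap the 2 libraries of a set were run too, 8 for each comparison, too few for a share under 0.05. With the set as a block, 4 of 8 gave as many lists as the real 3 for high against normal glucose (highest other 7), 5 of 8 as many as the real 6 for Hsp70 against high glucose (highest other 10), and 3 of 8 as many as the real 7 for Hsp70 against normal glucose (highest other 9). Without the block these were 7 of 8 for the real 2 (highest other 5), 4 of 8 for the real 5 (highest other 7) and 2 of 8 for the real 8 (highest other 8). Genes at an unadjusted p under 0.05, with the block, gave 1 of 8 for the real 636 (highest other 537), 8 of 8 for the real 305 (highest other 1451) and 6 of 8 for the real 587 (highest other 3646).

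The correlation of the high glucose and Hsp70 differences, -0.425, was matched or passed by 67 of 100 relabellings (lowest other -0.747), a draw separate from the one in the report, whose lowest was -0.776, so chance cannot be excluded there either. These relabellings mixed the file sets.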
